A study of Mus musculus with 20 samples.

How the data were processed

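Livers of mice fasted for 24 h were profiled by RNA sequencing in 20 libraries, 4 from each of 5 groups. Per the labels, the groups were controls that carried floxed Cpt1a, Cpt1b and Cpt2 alleles (Control) and mice with liver-specific loss of Cpt1a and Cpt1b (Cpt1DKO), of Cpt2 (Cpt2KO), of all of these (TKO), or of Cpt2 together with Ppara (Cpt2PparaDKO). Total RNA was extracted from frozen tissue and sequenced by a service provider, per the labels' protocols. The labels do not say whether the 4 libraries of a group came from 4 animals, so p-values measured the spread between libraries, which may be partly technical. All mutant groups were set against the same control group, so a difference of line or background between groups could not be separated from the genotype.

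The authors deposited a table of whole-number read counts per gene, not normalized, with Ensembl identifiers, symbols, biotypes and coordinates. HISAT2 and the build GRCm39, also written mm39, are named per the submitters' processing notes. The version of the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical paralogs could therefore not be told apart, and values for Mup, Cyp2c, Cyp4a, Saa, Gsta, Gstm, Acot1 to Acot3, haemoglobin and Serpina1 genes are uncertain for that reason. The authors also deposited tables of their own comparisons, with log2 fold changes and adjusted p-values per the file headers. The test behind those p-values is not given in the sources used here, and the tables served only for a comparison of calls. The deposited FPKM values and the authors' tables of Cpt2PparaDKO against TKO and against Cpt1DKO were not used here. Coordinates came from the count table, and the reference annotation of an older build was not used.

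The count table held 56748 genes, of which 31344 had a count above 0 in any library. Total counts per library ran from 14129595 to 36452673. Every count column was matched to a library by its title, which left 0 columns unmapped, and 0 rows named no gene. Genes were filtered with edgeR's filterByExpr (minimum count 10), which left 15669. Counts were scaled with TMM factors, and levels are given as CPM (counts scaled to a common library size), as mean ± SD over the 4 libraries of a group. One edgeR quasi-likelihood model with group as the only factor was fitted to all 20 libraries (edgeR 4.0.16, robust dispersions, biological coefficient of variation 0.233, prior degrees of freedom 6.27), so that the groups shared 1 estimate of spread per gene. Tests were two-sided, adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Unless another tool is named, every adjusted p of a gene comes from this test. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic.

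The comparisons were each mutant group against Control, Cpt2KO against Cpt1DKO, Cpt2PparaDKO against Cpt2KO, TKO against Cpt2KO, TKO against Cpt1DKO, and the interaction, in which the effect of losing Cpt2 in the absence of Cpt1a and Cpt1b was compared with its effect in their presence. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of 27 gene lists, 26 had at least 3 tested members and were tested with limma's camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the lists of a comparison. Camera compares a list with all other genes. The lists covered mitochondrial fatty acid oxidation, ketogenesis, peroxisomal oxidation and biogenesis, microsomal omega oxidation, canonical PPARalpha targets, lipid droplet and triglyceride storage, de novo lipogenesis, cholesterol synthesis and uptake, gluconeogenesis and fasting glucose, ATF4 and integrated stress response, NRF2 targets, bile acid synthesis and transport, urea cycle and nitrogen disposal, nuclear-encoded oxidative phosphorylation, mitochondrial DNA transcripts, acute phase, macrophage and Kupffer markers, endothelial markers, stellate and matrix markers, cholangiocyte markers, lymphocyte markers, neutrophil markers, erythroid transcripts, circadian clock, cell cycle and hepatocyte secreted proteins. The list of pancreas and adipose transcripts had 1 tested member and was not tested as a list. The 4 targeted genes were in none, and some genes stood in more than 1 list.

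Genes were named by a rule. It took the 10 largest rises and the 10 largest falls of a comparison among called protein-coding genes with a mean of at least 5 CPM, a symbol that is not a predicted-gene name, and all 4 libraries of one group above all 4 of the other. For TKO against Cpt2KO, TKO against Cpt1DKO and the interaction it took 5 each way, and the interaction had no condition on single libraries. It added the 4 targeted genes, 5 fasting genes (Fgf21, Pdk4, Cyp4a14, Acot1 and Plin2), another that is not reported here, and up to 4 members of each list with the smallest adjusted p.

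The pipeline was tested on simulated data for Cpt1DKO against Control, with counts drawn for 15309 genes from the means and sizes of the real libraries. The edgeR test called 19.4% of 67 genes changed 1.5-fold, 64.2% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, and 8 of its 128 calls (6.25%) were genes simulated without a change. DESeq2 called 23.9%, 68.7% and 98.5%. A 1.5-fold change was therefore often missed at this depth and number of libraries. Alternatives were size factors of the RLE kind, the DESeq2 Wald test (DESeq2 1.42.0), no expression filter beyond a count above 0, the replicate number as a block, sex as a term, only the 8 libraries compared, each library left out in turn, and for the lists an inter-gene correlation estimated from the data. Sex was read from Xist and the Y-linked genes. For the overlap of comparisons that share control libraries, unchanged groups were simulated 10 times and the 4 controls were split into pairs in all 6 ways. Other tools were R 4.3.3, the data.table package at version 1.17.8, Python 3.11.15 and matplotlib 3.10.9.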

Results

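Gene counts from 20 liver libraries of mice fasted for 24 h were compared between a control group and 4 groups lacking parts of the carnitine shuttle, which carries long-chain fatty acids into mitochondria for oxidation. CPT1, encoded in liver mainly by Cpt1a and in muscle mainly by Cpt1b, forms acylcarnitines at the outer mitochondrial membrane, and CPT2 turns them back into acyl-CoA at the inner membrane. PPARalpha, encoded by Ppara, is the nuclear receptor that drives the fasting programme of lipid genes. Each group held 4 libraries. Total counts were 14129595 to 20273303 in 19 libraries and 36452673 in Cpt2PparaDKO replicate 1. Within each group every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom from 12.5 to 168, so that no library was a copy of another. Albumin, the main secreted hepatocyte protein, took 5.42 ± 0.408% of counts in Control (SD, n = 4), 4.61 ± 0.228% in Cpt1DKO, 3.31 ± 1.09% in Cpt2KO, 2.79 ± 0.712% in TKO and 2.5 ± 0.666% in Cpt2PparaDKO.

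Xist, the transcript of the inactive X chromosome, reached 981 CPM in Cpt2KO replicate 3 and 1270 CPM in Cpt2PparaDKO replicate 4, and each of 4 Y-linked genes had at most 1 count there. These were the 2 libraries with a female pattern, and the other 18 had a male pattern. Sex-biased liver genes, such as those of the Mup and Cyp2a families, are affected by these libraries in every comparison, through a group's mean or the shared estimate of spread.

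The targeted genes were examined first. Cpt1a (ENSMUSG00000024900, chromosome 19, 3372334 to 3435733, GRCm39, plus strand) stood at 1040 ± 76.6 CPM in Control (SD, n = 4), 155 ± 12.2 in Cpt1DKO and 137 ± 12.7 in TKO, against 1380 ± 191 in Cpt2KO and 840 ± 251 in Cpt2PparaDKO. Cpt2 (ENSMUSG00000028607, chromosome 4, 107761178 to 107780807, minus strand) stood at 249 ± 26.2 CPM in Control, 258 ± 74.3 in Cpt1DKO, 131 ± 23.6 in Cpt2KO, 103 ± 11.7 in TKO and 33.9 ± 4.86 in Cpt2PparaDKO. Ppara (ENSMUSG00000022383, chromosome 15, 85619184 to 85687020, plus strand) stood at 233 ± 46.1 CPM in Control, 238 ± 64.3 in Cpt1DKO, 267 ± 84.3 in Cpt2KO, 322 ± 79.4 in TKO and 73.2 ± 13 in Cpt2PparaDKO. Cpt1b (ENSMUSG00000078937, chromosome 15, 89300608 to 89310066, minus strand) was near the floor in all groups, at 0.543 ± 0.215 CPM in Control, 0.881 ± 0.217 in Cpt1DKO, 3.91 ± 1.74 in Cpt2KO, 2.8 ± 0.308 in TKO and 0.58 ± 0.2 in Cpt2PparaDKO. Its count was thus not lower where the label says that it was targeted, and it does not check those labels. Counts were made over whole genes, and a floxed allele removes only part of a gene, so counts left in a mutant group can come from the remaining exons or from other cells.

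**Figure D1:**
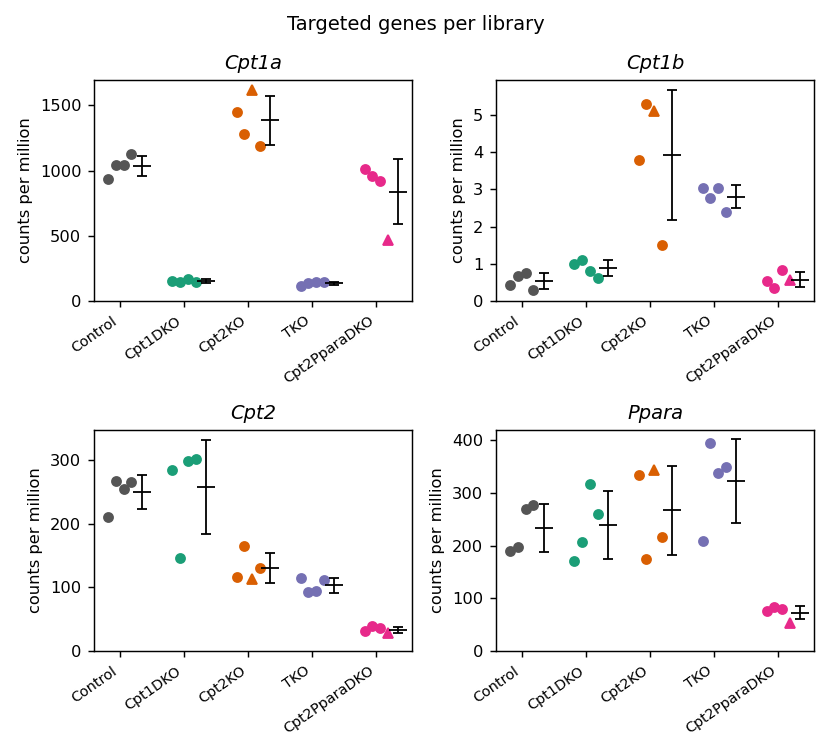
CPM (linear axes from 0) of Cpt1a, Cpt1b, Cpt2 and Ppara by group, with a dot for each library, a triangle for each library with high Xist, and a bar for the mean ± SD of 4 libraries. Cpt1a stood at 155 ± 12.2 in Cpt1DKO and 137 ± 12.7 in TKO against 1040 ± 76.6 in Control, and Cpt2 was lowest in Cpt2PparaDKO at 33.9 ± 4.86.

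**Figure D2:**
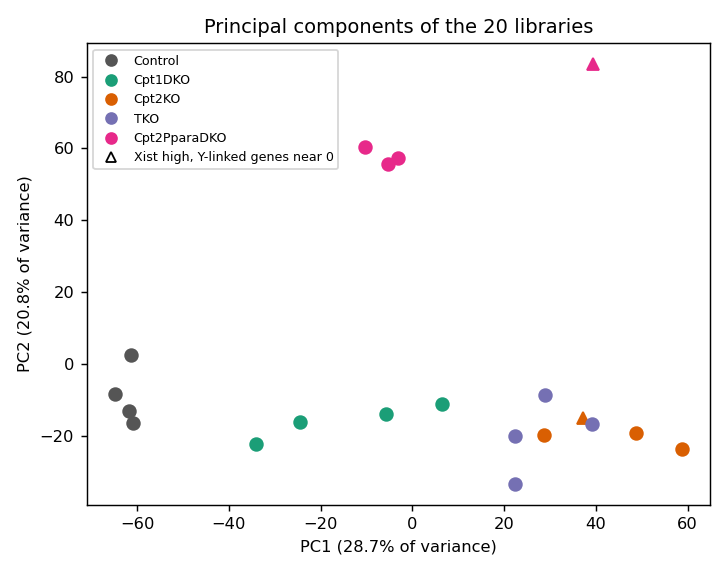
Principal components of the log2 CPM of 15669 genes, with component 1 (28.7% of the variance) on the horizontal and component 2 (20.8%) on the vertical axis, a symbol for each library coloured by group, and a triangle for each library with high Xist. The Control libraries lay at the negative end of component 1, Cpt2PparaDKO at the positive end of component 2, and Cpt2PparaDKO replicate 4 apart from the rest of its group.

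Loss of Cpt1a and Cpt1b, the question of the first comparison, raised genes of lipid storage and PPARalpha targets. Cidec, which enlarges lipid droplets, rose from 24.3 ± 4.19 CPM in Control to 302 ± 64.8 in Cpt1DKO (SD, n = 4; log2 fold change 3.63, SE 0.22, adjusted p = 2.7e-09). Plin2, a coat protein of lipid droplets, rose from 455 ± 81.9 to 1420 ± 309 CPM (1.65, SE 0.23, adjusted p = 2.4e-04), and Apoa4, an apolipoprotein of triglyceride export, from 656 ± 279 to 5850 ± 1430 CPM (3.16, SE 0.35, adjusted p = 2.4e-05). Fgf21, a hormone of the fasted liver, rose from 3.45 ± 1.92 to 29.6 ± 12 CPM (3.12, SE 0.54, adjusted p = 0.00354). Thrsp, an activator of fatty acid synthesis, fell from 38.2 ± 10.4 to 5.62 ± 1.79 CPM (-2.77, SE 0.30, adjusted p = 2.4e-05).

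Of 36 measured canonical PPARalpha targets, 14 rose in Cpt1DKO and 22 were not called (20 rose adjusted over the list alone), with a median log2 fold change of 0.72 (camera adjusted p = 5.2e-22; adjusted p = 0.00388 with an estimated correlation). Acot1, an acyl-CoA thioesterase with close paralogs, rose by 1.76 (SE 0.20), Ehhadh, a peroxisomal oxidation enzyme, by 1.54 (SE 0.22) and Pdk4, which blocks the entry of pyruvate into the citric acid cycle, by 3.02 (SE 0.48). Among 19 lipid droplet genes, 7 rose and 12 were not called (9 rose and 1 fell over the list alone; median 0.48, adjusted p = 1.2e-11, and 0.00208 with an estimated correlation). Its members included the lipase gene Pnpla2 (1.07, SE 0.16) and its inhibitor Hilpda (1.84, SE 0.29). Of 22 genes of mitochondrial fatty acid oxidation, 5 rose (6 over the list alone; median 0.23, adjusted p = 3.5e-04, but 0.539 with an estimated correlation). Its members included the carnitine transporter gene Slc22a5 (0.70, SE 0.15) and Hadhb of the trifunctional protein (0.57, SE 0.12). Of 23 genes of the ATF4 and integrated stress response, 4 rose (4 over the list alone; median 0.42, adjusted p = 0.00423, but 0.437 with an estimated correlation). Its members included Gdf15, a stress hormone (2.32, SE 0.49).

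Lipid synthesis genes were lower in Cpt1DKO. Of 25 genes of cholesterol synthesis and uptake, 8 fell (21 adjusted over the list alone; median -0.87, adjusted p = 1.8e-12, but 0.197 with an estimated correlation). Sc5d, a late enzyme of the pathway, was at -0.85 (SE 0.18). Of 16 de novo lipogenesis genes, 5 fell, 2 rose and 9 were not called (8 and 3 over the list alone; median -0.51, adjusted p = 5.2e-04, but 0.128 with an estimated correlation). Srebf1, the main activator of the pathway, fell by 1.57 (SE 0.19) and Acly, which makes cytosolic acetyl-CoA, fell by 0.98 (SE 0.13), while Acacb, whose product makes the malonyl-CoA that inhibits CPT1, rose by 1.38 (SE 0.19). Of 20 acute phase genes, 5 fell (7 fell and 1 rose over the list alone; median -0.59, adjusted p = 9.8e-06, but 0.128 with an estimated correlation). Of 24 hepatocyte secreted proteins, 5 fell and 1 rose (9 and 3 over the list alone; median -0.35, adjusted p = 0.00835, but 0.539 with an estimated correlation). Circadian clock genes were lower as a list (2 of 17 fell, 4 over the list alone; median -0.36, adjusted p = 0.00263, but 0.32 with an estimated correlation). Bhlhe40, a repressor in the clock, was at -1.28 (SE 0.27). Markers of endothelial cells (2 of 14 rose, 4 over the list alone; median 0.44, adjusted p = 1.6e-05, but 0.372 with an estimated correlation) were higher as a list. So were markers of stellate cells and matrix (2 of 20 rose, 2 over the list alone; median 0.36, adjusted p = 0.00326, but 0.197 with an estimated correlation). The median of endothelial markers was 0.77 without Control replicate 1, and that of the circadian clock was -0.67 without Cpt1DKO replicate 3.

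Further lists were called with fewer members moving. The list of ketogenesis (1 of 6 rose, 1 adjusted over the list alone; median 0.26, adjusted p = 0.0473, but 0.32 with an estimated correlation) lost its call without Control replicate 1 or 3 or Cpt1DKO replicate 3 or 4 (adjusted p up to 0.171). That of peroxisomal oxidation and biogenesis (4 of 23 rose and 1 fell, 4 and 1 over the list alone; median 0.09, adjusted p = 0.0224, but 0.545 with an estimated correlation) lost it without Control replicate 1 or Cpt1DKO replicate 3 or 4 (up to 0.174). Its median was 0.23 and 0.20 without Control replicate 3 or 4, 0.20 and 0.18 without Cpt1DKO replicate 1 or 2, and 0.03 without Cpt1DKO replicate 3 or 4. The list of bile acid synthesis and transport (1 of 18 fell, 3 over the list alone; median -0.32, adjusted p = 0.0224, but 0.539 with an estimated correlation) lost it without Cpt1DKO replicate 2 (adjusted p = 0.0693). That of urea cycle and nitrogen disposal (2 of 14 fell, 2 over the list alone; median -0.15, adjusted p = 0.0476, but 0.545 with an estimated correlation) lost it without Control replicate 2 or 3 or Cpt1DKO replicate 2, 3 or 4 (up to 0.102). Its median was -0.07 without Cpt1DKO replicate 2 and -0.23 without Cpt1DKO replicate 3.

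In total, edgeR called 869 genes between Cpt1DKO and Control, 383 higher and 486 lower, and camera called 15 of 26 lists. The count was 473, 470 and 481 without Control replicate 2, 3 or 4 and 288 and 309 without Cpt1DKO replicate 1 or 2. Among the 20 genes with the largest changes, Cpt1a, Thrsp, Apoa4, Cgref1, Cidec, Cntnap1, Dusp8 and Lepr kept their call whichever library was left out, and the other 12 lost it in 2 to 7 of the 8 fits.

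Loss of Cpt2 gave 5228 called genes against Control, where loss of Cpt1a and Cpt1b had given 869, and PPARalpha targets and lipid droplet genes again rose. Pdk4 rose from 8.47 ± 3.32 CPM in Control to 770 ± 187 in Cpt2KO (SD, n = 4; log2 fold change 6.51, SE 0.56, adjusted p = 3.9e-07), and Fabp3, a fatty acid binding protein of heart and muscle, from 0.107 ± 0.0852 to 20.3 ± 8.11 CPM (7.46, SE 0.82, adjusted p = 3.1e-06). Acot2, the mitochondrial thioesterase with a close paralog in Acot1, rose from 12.3 ± 3.63 to 357 ± 145 CPM (4.86, SE 0.40, adjusted p = 1.9e-07). Gpnmb, a gene of lipid-laden macrophages, rose from 0.249 ± 0.257 to 38 ± 13.7 CPM (7.22, SE 0.48, adjusted p = 9.8e-09), and Fgf21 from 3.45 ± 1.92 to 74.9 ± 23.9 CPM (4.46, SE 0.56, adjusted p = 1.8e-05). Akr1d1, a reductase of bile acid synthesis, fell from 272 ± 29.5 to 12.2 ± 11.2 CPM (-4.47, SE 0.60, adjusted p = 3.6e-05).

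Canonical PPARalpha targets rose in 25 of 36 cases in Cpt2KO, and 1 fell (28 and 1 adjusted over the list alone; median 1.54, adjusted p = 8.3e-22, and 0.00425 with an estimated correlation). Plin2 rose by 3.11 (SE 0.24), Acot1 by 3.35 (SE 0.22) and Pex11a, which promotes the division of peroxisomes, by 2.18 (SE 0.17). Of 19 lipid droplet genes, 13 rose (14 rose and 1 fell over the list alone; median 1.15, adjusted p = 1.9e-13, and 0.00149 with an estimated correlation). Cidec was at 4.30 (SE 0.23). Of 22 genes of mitochondrial fatty acid oxidation, 14 rose and 1 fell (14 and 1 over the list alone; median 0.52, adjusted p = 8.4e-06, but 0.428 with an estimated correlation). Peroxisomal genes rose in 13 of 23 cases and fell in 4 (14 and 4 over the list alone; median 0.56, adjusted p = 0.00263, but 0.428 with an estimated correlation). Ehhadh was at 2.70 (SE 0.23) and Pecr, a trans-2-enoyl-CoA reductase, at -2.51 (SE 0.20). Of 23 genes of the ATF4 and integrated stress response, 13 rose and 2 fell (14 and 2 over the list alone; median 0.79, adjusted p = 5.5e-05, but 0.246 with an estimated correlation). Gdf15 rose by 4.14 (SE 0.50), while Cth, of cysteine synthesis, fell by 3.43 (SE 0.42). Ketogenesis genes were not called as a list (2 of 6 rose, 2 over the list alone; median 0.10, adjusted p = 0.278).

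Several groups of hepatocyte function genes were lower in Cpt2KO. Of 18 genes of bile acid synthesis and transport, 11 fell and 1 rose (12 and 1 adjusted over the list alone; median -1.20, adjusted p = 8.4e-06, but 0.246 with an estimated correlation). The bile salt export pump Abcb11 was at -3.68 (SE 0.39) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -3.58 (SE 0.46). Of 14 urea cycle and nitrogen disposal genes, 11 fell (11 over the list alone; median -0.77, adjusted p = 8.4e-06, but 0.246 with an estimated correlation). Its members included Otc at -2.44 (SE 0.34) and Glul, glutamine synthetase, at -1.97 (SE 0.28). Cholesterol genes fell in 17 of 25 cases (17 over the list alone; median -0.90, adjusted p = 1.5e-06, but 0.421 with an estimated correlation). Of 16 lipogenesis genes, 10 fell and 4 rose (10 and 4 over the list alone; median -1.05, adjusted p = 0.00894, but 0.246 with an estimated correlation). Thrsp was at -3.88 (SE 0.32). Acute phase genes fell in 11 of 20 cases and 1 rose (13 and 1 over the list alone; median -0.80, adjusted p = 9.3e-06, but 0.173 with an estimated correlation). The fibrinogen chain gene Fgb was at -1.76 (SE 0.21) and its partner Fga at -2.43 (SE 0.30). Of 24 hepatocyte secreted proteins, 16 fell and 3 rose (17 and 3 over the list alone; median -0.69, adjusted p = 5.5e-05, but 0.322 with an estimated correlation). The list of the circadian clock (5 of 17 fell, 5 over the list alone; median -0.43, adjusted p = 0.0438, but 0.491 with an estimated correlation) lost its call without Control replicate 3 or 4 or Cpt2KO replicate 2 or 4 (adjusted p up to 0.0796). It was lost as well with sex as a term and without both female libraries (adjusted p = 0.0618 and 0.0596). Of 20 NRF2 targets, 7 rose and 3 fell (8 and 4 over the list alone), and the list was not called (median 0.39, adjusted p = 0.265). Nor were lists of macrophages (median -0.03, mean 0.55, adjusted p = 0.197), endothelial cells (0.11, adjusted p = 0.587), stellate cells and matrix (0.12, adjusted p = 0.446), cholangiocytes (-0.81, adjusted p = 0.106), lymphocytes (-0.21, adjusted p = 0.985), neutrophils (-0.01, adjusted p = 0.994) or erythroid transcripts (1.08, adjusted p = 0.424). The same held for cell cycle genes (median 0.07, mean -0.11, adjusted p = 0.985), nuclear-encoded oxidative phosphorylation (0.03, adjusted p = 0.616), mitochondrial DNA transcripts (-0.22, adjusted p = 0.451), gluconeogenesis (-0.63, adjusted p = 0.181) and microsomal omega oxidation (median 0.02, mean -0.17, adjusted p = 0.446). Adrb3, the beta-3 adrenergic receptor and the only tested gene of the pancreas and adipose list, fell by 3.78 (SE 0.55, adjusted p = 4.0e-05).

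In Cpt2KO against Control 5228 genes were called, 2538 higher and 2690 lower, and 12 of 26 lists. Of the 20 genes with the largest changes, 18 kept their call whichever library was left out. Mup8 (-8.89, SE 2.11) was at -1.94 without Control replicate 2, with an adjusted p of 0.124, and Mup10 lost its call without Control replicate 3 or any Cpt2KO library (adjusted p up to 0.508).

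TKO, which lacks both steps of the shuttle, resembled Cpt2KO in the genes that led. Against Control, Pdk4 rose from 8.47 ± 3.32 to 562 ± 297 CPM in TKO (SD, n = 4; log2 fold change 6.05, SE 0.55, adjusted p = 1.2e-06), Fabp3 from 0.107 ± 0.0852 to 13.4 ± 9.43 CPM (6.87, SE 0.82, adjusted p = 1.4e-05) and Gpnmb from 0.249 ± 0.257 to 23.7 ± 3.18 CPM (6.54, SE 0.48, adjusted p = 5.0e-08). Nupr1, a stress-induced chromatin protein, rose from 0.553 ± 0.262 to 13.7 ± 6.32 CPM (4.62, SE 0.80, adjusted p = 5.1e-04). Serpina6, the corticosteroid-binding globulin, fell from 115 ± 40.1 to 4.95 ± 0.809 CPM (-4.53, SE 0.70, adjusted p = 2.1e-04), and Akr1d1 from 272 ± 29.5 to 12.7 ± 6.19 CPM (-4.43, SE 0.60, adjusted p = 6.1e-05).

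Of 36 canonical PPARalpha targets, 23 rose in TKO and 1 fell (25 and 2 adjusted over the list alone; median 1.00, adjusted p = 5.6e-18, and 0.00831 with an estimated correlation). Of 19 lipid droplet genes, 13 rose (13 over the list alone; median 1.15, adjusted p = 1.2e-12, and 0.00146 with an estimated correlation). Cidec rose by 4.27 (SE 0.23), Plin2 by 2.74 (SE 0.23) and Hilpda by 2.75 (SE 0.29). Genes of the ATF4 and integrated stress response rose in 11 of 23 cases and fell in 2 (13 and 2 over the list alone; median 0.96, adjusted p = 2.6e-05, but 0.189 with an estimated correlation). Their median was 0.63 without TKO replicate 1. Of 20 NRF2 targets, 9 rose and 1 fell (10 and 2 over the list alone; median 0.50, adjusted p = 0.00703, but 0.57 with an estimated correlation). The carbonyl reductase gene Cbr3 was at 3.94 (SE 0.61). The urea cycle list was lower (11 of 14 fell, 11 over the list alone; median -0.83, adjusted p = 1.2e-06, but 0.17 with an estimated correlation). So were secreted proteins (15 of 24 fell and 1 rose, 15 and 2 over the list alone; median -0.77, adjusted p = 1.2e-06, but 0.172 with an estimated correlation). Bile acid genes fell in 11 of 18 cases (12 over the list alone), by a median of 1.00 on the log2 scale (adjusted p = 5.8e-06, but 0.172 with an estimated correlation). Cholesterol genes fell in 17 of 25 cases (20 over the list alone; median -0.97, adjusted p = 1.4e-08, but 0.284 with an estimated correlation). Acute phase genes fell in 12 of 20 cases and 2 rose (12 and 2 over the list alone; median -0.83, adjusted p = 4.6e-05, but 0.172 with an estimated correlation). Of 16 lipogenesis genes, 8 fell and 4 rose (8 and 4 over the list alone; median -1.06, adjusted p = 0.00153, but 0.17 with an estimated correlation). The list of mitochondrial fatty acid oxidation (7 of 22 rose and 2 fell, 7 and 2 over the list alone; median 0.28, adjusted p = 0.0171, but 0.756 with an estimated correlation) lost its call without Control replicate 1 (adjusted p = 0.0708).

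In TKO against Control 4287 genes were called, 2030 higher and 2257 lower, and 11 of 26 lists. Of the 20 genes with the largest changes, 19 kept their call whichever library was left out, and Mup8 (-8.41, SE 2.04) was at -1.46 without Control replicate 2, with an adjusted p of 0.268. Mitochondrially encoded genes took 6.68 ± 0.992% of counts in TKO against 5.23 ± 0.552% in Control (SD, n = 4).

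Loss of Ppara together with Cpt2 turned the lipid oxidation genes below Control. Cyp4a14, a microsomal fatty acid hydroxylase with close paralogs, fell from 8250 ± 696 CPM in Control to 446 ± 129 in Cpt2PparaDKO (SD, n = 4; log2 fold change -4.21, SE 0.22, adjusted p = 4.4e-11). Acot1 fell from 146 ± 16.8 to 80.8 ± 22 CPM (-0.85, SE 0.20, adjusted p = 0.00257). Plin2 rose from 455 ± 81.9 to 1210 ± 382 CPM (1.41, SE 0.22, adjusted p = 8.1e-05), and Pdk4 from 8.47 ± 3.32 to 40.8 ± 14.2 CPM (2.27, SE 0.47, adjusted p = 0.00151). Nupr1 rose from 0.553 ± 0.262 to 106 ± 88.8 CPM (7.59, SE 0.83, adjusted p = 7.4e-06) and Mmp12, a macrophage elastase, from 0.316 ± 0.201 to 23.7 ± 4.56 CPM (6.22, SE 0.45, adjusted p = 6.7e-09).

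Of 36 canonical PPARalpha targets, 24 fell and 5 rose in Cpt2PparaDKO (26 and 7 adjusted over the list alone; median -1.41, adjusted p = 8.0e-17, and 0.0142 with an estimated correlation). Of 23 peroxisomal genes, 19 fell (21 over the list alone; median -1.38, adjusted p = 4.5e-21, and 0.0101 with an estimated correlation). Of 14 microsomal omega oxidation genes, 13 fell (14 over the list alone; median -1.85, adjusted p = 2.6e-19, and 0.00599 with an estimated correlation). Mitochondrial fatty acid oxidation genes fell in 21 of 22 cases and 1 rose (21 and 1 over the list alone; median -1.28, adjusted p = 2.7e-23, but 0.0501 with an estimated correlation). The carnitine carrier Slc25a20 was at -1.92 (SE 0.13). Of 29 nuclear-encoded oxidative phosphorylation genes, 27 fell (28 over the list alone; median -0.52, adjusted p = 5.4e-10, but 0.169 with an estimated correlation). Its members included Atp5a1 of ATP synthase (-0.74, SE 0.12). Of 6 ketogenesis genes, 3 fell and 1 rose (3 and 1 over the list alone; median -0.67, adjusted p = 0.0125, but 0.121 with an estimated correlation). Lipid droplet genes went both ways, with 8 of 19 lower and 6 higher (9 and 7 over the list alone; median -0.46, adjusted p = 0.433).

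Secreted proteins were lower as a list in Cpt2PparaDKO (18 of 24 fell and 1 rose, 19 and 1 adjusted over the list alone; median -0.86, adjusted p = 1.1e-08, but 0.0758 with an estimated correlation). So were genes of the urea cycle (11 of 14 fell, 11 over the list alone; median -0.83, adjusted p = 1.2e-06, but 0.085 with an estimated correlation) and of bile acids (12 of 18 fell, 13 over the list alone; median -1.08, adjusted p = 1.3e-06, but 0.0878 with an estimated correlation). Genes of gluconeogenesis and fasting glucose fell in 10 of 17 cases and 2 rose (10 and 2 over the list alone; median -1.07, adjusted p = 0.00108, but 0.278 with an estimated correlation). Their median was -0.71 without Control replicate 3. Pcx, pyruvate carboxylase, was at -1.22 (SE 0.21). Genes of the circadian clock fell in 8 of 17 cases and 1 rose (8 and 1 over the list alone; median -0.65, adjusted p = 9.9e-04, but 0.164 with an estimated correlation). Lipogenesis genes fell in 9 of 16 cases and 1 rose (10 and 1 over the list alone; median -0.48, adjusted p = 5.7e-04, but 0.0758 with an estimated correlation). Genes of the ATF4 and integrated stress response rose in 15 of 23 cases and 2 fell (18 and 2 over the list alone; median 1.34, adjusted p = 1.4e-08, but 0.0758 with an estimated correlation). NRF2 targets rose in 13 of 20 cases (15 over the list alone; median 1.08, adjusted p = 2.2e-06, but 0.143 with an estimated correlation). Nqo1, a quinone reductase, was at 1.40 (SE 0.24). Macrophage markers rose in 8 of 20 cases (8 over the list alone; median 0.55, adjusted p = 1.8e-06, but 0.169 with an estimated correlation). Its members included Cd68 at 3.14 (SE 0.27) and the monocyte chemokine Ccl2 at 3.53 (SE 0.70). Stellate and matrix genes rose in 9 of 20 cases and 1 fell (10 and 1 over the list alone; median 0.49, adjusted p = 4.2e-04, but 0.0758 with an estimated correlation). Col1a1 was at 1.38 (SE 0.27). The list of neutrophil markers (2 of 4 rose, 3 over the list alone; median 1.18, adjusted p = 0.0458, but 0.229 with an estimated correlation) lost its call without Cpt2PparaDKO replicate 2, 3 or 4 (adjusted p = 0.0523, 0.0848 and 0.0644). It was lost as well with sex as a term, without both female libraries and with only the 8 libraries compared (adjusted p = 0.0743, 0.0714 and 0.0569). Cholangiocyte markers stood 1.85 log2 units above the mean of the other libraries of the group in replicate 4, against -0.10 to 0.11 for those libraries.

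In Cpt2PparaDKO against Control 5091 genes were called, 2328 higher and 2763 lower, and 17 of 26 lists. Of the 20 genes with the largest changes, Mup15 lost its call without Control replicate 4 or any Cpt2PparaDKO library (adjusted p up to 0.127). Cyp2a4 was at 8.83 (SE 2.01) and at 5.54 without the female library, Cpt2PparaDKO replicate 4, and Mup8 at -10.58 (SE 2.30) and at -3.72 without Control replicate 2, where both were still called.

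**Figure D3:**
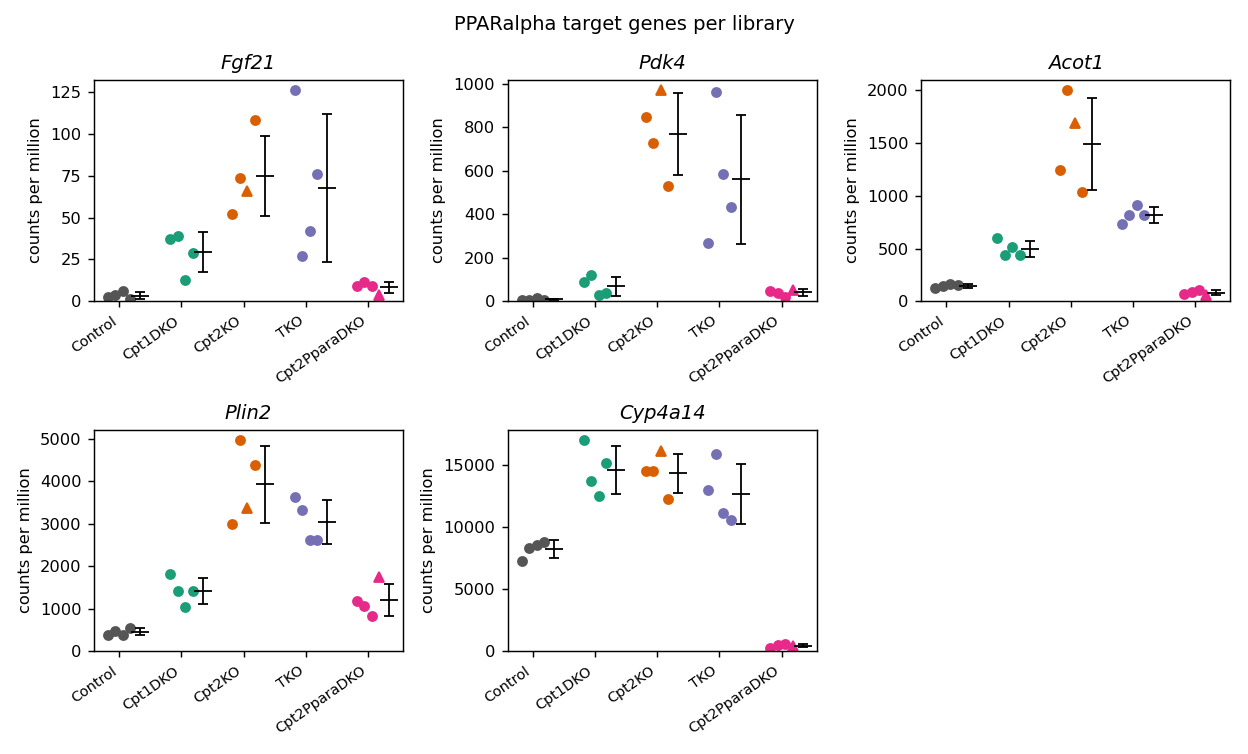
CPM (linear axes from 0) of Fgf21, Pdk4, Acot1, Plin2 and Cyp4a14 by group, with a dot for each library, a triangle for each library with high Xist, and a bar for the mean ± SD of 4 libraries. Pdk4 stood at 8.47 ± 3.32 in Control, 68.5 ± 42.4 in Cpt1DKO, 770 ± 187 in Cpt2KO, 562 ± 297 in TKO and 40.8 ± 14.2 in Cpt2PparaDKO.

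Loss of the matrix step was compared directly with loss of the outer step. Pdk4 stood at 770 ± 187 CPM in Cpt2KO and 68.5 ± 42.4 in Cpt1DKO (SD, n = 4; log2 fold change 3.49, SE 0.48, adjusted p = 2.4e-04), and Fabp3 at 20.3 ± 8.11 against 0.233 ± 0.151 CPM (6.33, SE 0.74, adjusted p = 6.0e-05). Gpnmb stood at 38 ± 13.7 CPM against 1.68 ± 0.695 CPM (4.47, SE 0.38, adjusted p = 1.2e-06). Cyp7a1 was lower, at 15 ± 7.48 against 149 ± 35.4 CPM (-3.31, SE 0.45, adjusted p = 2.4e-04), as was Bhmt, which remethylates homocysteine, at 843 ± 411 against 6390 ± 1090 CPM (-2.92, SE 0.36, adjusted p = 5.9e-05). Fgf21 (1.34, SE 0.48, adjusted p = 0.0725) passed in the authors' table, not here.

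Of 36 PPARalpha targets, 15 were higher in Cpt2KO than in Cpt1DKO and 1 lower (19 and 1 adjusted over the list alone; median 0.65, adjusted p = 3.3e-10, but 0.101 with an estimated correlation). Of 19 lipid droplet genes, 10 were higher (11 over the list alone; median 0.61, adjusted p = 3.7e-07, and 0.0299 with an estimated correlation). Mitochondrial fatty acid oxidation genes were higher in 5 of 22 cases (7 over the list alone; median 0.30, adjusted p = 6.7e-04, but 0.598 with an estimated correlation). So were 6 of 23 genes of the ATF4 and integrated stress response, with 1 lower (11 and 2 over the list alone; median 0.80, adjusted p = 6.7e-04, but 0.442 with an estimated correlation). The median was 1.31 without Cpt1DKO replicate 2. Bile acid genes were lower in 8 of 18 cases (8 over the list alone; median -0.69, adjusted p = 2.2e-06, but 0.244 with an estimated correlation). Urea cycle genes were lower in 6 of 14 cases (10 over the list alone; median -0.77, adjusted p = 2.1e-06, but 0.227 with an estimated correlation), and gluconeogenesis genes were lower in 4 of 17 and higher in 1 (6 and 1 over the list alone; median -0.83, adjusted p = 7.6e-04, but 0.442 with an estimated correlation). Of 20 acute phase genes, 7 were lower and 3 higher (8 and 3 over the list alone), and the list was called lower with a median of -0.22 although its mean was 0.01 (adjusted p = 0.00722, but 0.442 with an estimated correlation). That median was -0.37 without Cpt2KO replicate 2 and -0.12 without Cpt2KO replicate 3. NRF2 targets were higher in 4 of 20 cases and lower in 1 (9 and 1 over the list alone; median 0.46, adjusted p = 0.00624, but 0.598 with an estimated correlation). Hepatocyte secreted proteins were lower in 5 of 24 and higher in 1 (7 and 1 over the list alone; median -0.31, adjusted p = 9.2e-04, but 0.442 with an estimated correlation).

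Markers of other liver cells also differed between Cpt2KO and Cpt1DKO. The endothelial markers were lower as a list (1 of 14 lower, 0 adjusted over the list alone; median -0.41, adjusted p = 0.00624, but 0.598 with an estimated correlation). Its called member Pecam1, an adhesion molecule (-0.75, adjusted p = 0.0371), lost its call without Cpt1DKO replicate 1 or 2 or Cpt2KO replicate 1, 2 or 4 (adjusted p up to 0.12). The cholangiocyte markers (1 of 12 lower, 1 over the list alone; median -0.86, adjusted p = 0.0176, but 0.442 with an estimated correlation) lost their call without Cpt1DKO replicate 2 (median -0.40, adjusted p = 0.0976). Sox9, a transcription factor of bile duct cells, was at -1.63 (adjusted p = 0.0026) and kept its call. The list of peroxisomal oxidation and biogenesis (6 of 23 higher and 2 lower, 6 and 2 over the list alone; median 0.25, adjusted p = 0.0159, but 0.598 with an estimated correlation) lost its call without Cpt1DKO replicate 2 (adjusted p = 0.198). The list of macrophage and Kupffer markers (3 of 20 higher, 3 over the list alone; median 0.21, adjusted p = 0.00722, but 0.598 with an estimated correlation) lost its call without the female library, Cpt2KO replicate 3 (median -0.17, adjusted p = 0.292). It was lost as well with sex as a term and without both female libraries (median 0.02 and -0.17, adjusted p = 0.0657 and 0.21). Its median was 0.11, 0.08 and 0.40 without Cpt1DKO replicate 1, Cpt2KO replicate 1 or Cpt2KO replicate 4, and 0.10 with the replicate number as a block.

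Between Cpt2KO and Cpt1DKO 2212 genes were called, 1161 higher and 1051 lower in Cpt2KO, and 14 of 26 lists. The count was 1435 and 1337 without Cpt1DKO replicate 1 or 4 and 1192 without Cpt2KO replicate 2. Of the 20 genes with the largest differences, Cyp2a4 (6.84, SE 2.09) lost its call in 6 of 8 fits (adjusted p up to 0.116), without any Cpt1DKO library or Cpt2KO replicate 2 or 3.

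Cpt2PparaDKO against Cpt2KO cannot isolate PPARalpha, as Cpt2 fell too (33.9 against 131 CPM). Ehhadh stood at 252 ± 46.7 CPM in Cpt2PparaDKO and 11300 ± 1510 in Cpt2KO (SD, n = 4; log2 fold change -5.48, SE 0.26, adjusted p = 3.8e-12), Cyp4a14 at 446 ± 129 against 14300 ± 1580 CPM (-5.01, SE 0.23, adjusted p = 3.8e-12) and Retsat, a retinol saturase, at 169 ± 55.2 against 4460 ± 336 CPM (-4.72, SE 0.22, adjusted p = 3.8e-12). Fgf21 stood at 8.39 ± 3.19 against 74.9 ± 23.9 CPM (-3.16, SE 0.51, adjusted p = 2.7e-04) and Pdk4 at 40.8 ± 14.2 against 770 ± 187 CPM (-4.24, SE 0.50, adjusted p = 8.8e-06). Sdf2l1, an endoplasmic reticulum chaperone cofactor, was higher, at 64 ± 13.1 against 5.34 ± 2.5 CPM (3.57, SE 0.38, adjusted p = 2.1e-06), as was Mmp12 at 23.7 ± 4.56 against 0.451 ± 0.296 CPM (5.74, SE 0.43, adjusted p = 4.0e-09).

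Of 36 PPARalpha targets, 35 were lower in Cpt2PparaDKO than in Cpt2KO (35 adjusted over the list alone; median -2.85, adjusted p = 1.0e-81, and 1.6e-05 with an estimated correlation). Lower too were 20 of 22 mitochondrial fatty acid oxidation genes (21 over the list alone; median -1.84, adjusted p = 1.4e-54, and 0.00182 with an estimated correlation). The same held for 19 of 23 peroxisomal genes with 1 higher (20 and 1 over the list alone; median -2.06, adjusted p = 1.5e-37, and 3.6e-04 with an estimated correlation) and 16 of 19 lipid droplet genes (16 over the list alone; median -2.05, adjusted p = 1.3e-20, and 9.3e-05 with an estimated correlation). The same direction held for 8 of 14 microsomal genes with 1 higher (10 and 1 over the list alone; median -1.94, adjusted p = 4.5e-15, and 0.00439 with an estimated correlation) and 4 of 6 ketogenesis genes (4 over the list alone; median -0.97, adjusted p = 4.6e-05, and 0.0157 with an estimated correlation). Acute phase genes were higher in 12 of 20 cases (16 over the list alone; median 1.02, adjusted p = 2.2e-10, and 0.0106 with an estimated correlation). The serum amyloid P gene Apcs was at 2.04 (SE 0.23) and haemopexin, Hpx, at 1.33 (SE 0.17). Cholesterol genes were higher in 17 of 25 cases and lower in 1 (18 and 1 over the list alone; median 0.85, adjusted p = 2.6e-06, but 0.363 with an estimated correlation). Fdps was at 2.12 (SE 0.40). Oxidative phosphorylation genes were lower in 25 of 29 cases (26 over the list alone; median -0.57, adjusted p = 3.9e-13, but 0.187 with an estimated correlation). Markers of stellate cells and matrix were higher in 6 of 20 cases (7 over the list alone; median 0.45, adjusted p = 0.00902, but 0.209 with an estimated correlation). The macrophage and Kupffer markers were higher in 6 of 20 (6 over the list alone; median 0.51, adjusted p = 9.9e-04, but 0.452 with an estimated correlation). Their median was 0.90 and 0.28 without Cpt2KO replicate 3 or 4.

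Other lists were called less firmly between Cpt2PparaDKO and Cpt2KO. NRF2 targets were higher in 7 of 20 cases and lower in 3 (8 and 4 adjusted over the list alone; median 0.31, adjusted p = 0.00111, but 0.363 with an estimated correlation). Their call was lost without Cpt2KO replicate 3 (median 0.10, adjusted p = 0.0544) and without both female libraries (0.09, adjusted p = 0.215). The neutrophil markers were higher in 3 of 4 cases (4 over the list alone; median 1.33, adjusted p = 0.0452, but 0.333 with an estimated correlation). Their call was lost without Cpt2PparaDKO replicate 3 or 4 (adjusted p = 0.0578 and 0.0964), with sex as a term (0.0577) and without both female libraries (0.0802).

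Between Cpt2PparaDKO and Cpt2KO 3822 genes were called, 1903 higher and 1919 lower, and 13 of 26 lists. All 20 genes with the largest differences kept their call whichever library was left out, although Lcn2, at 3.69 (SE 0.78), was at 2.37 without Cpt2PparaDKO replicate 4. Each group held 1 female library.

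**Figure D4:**
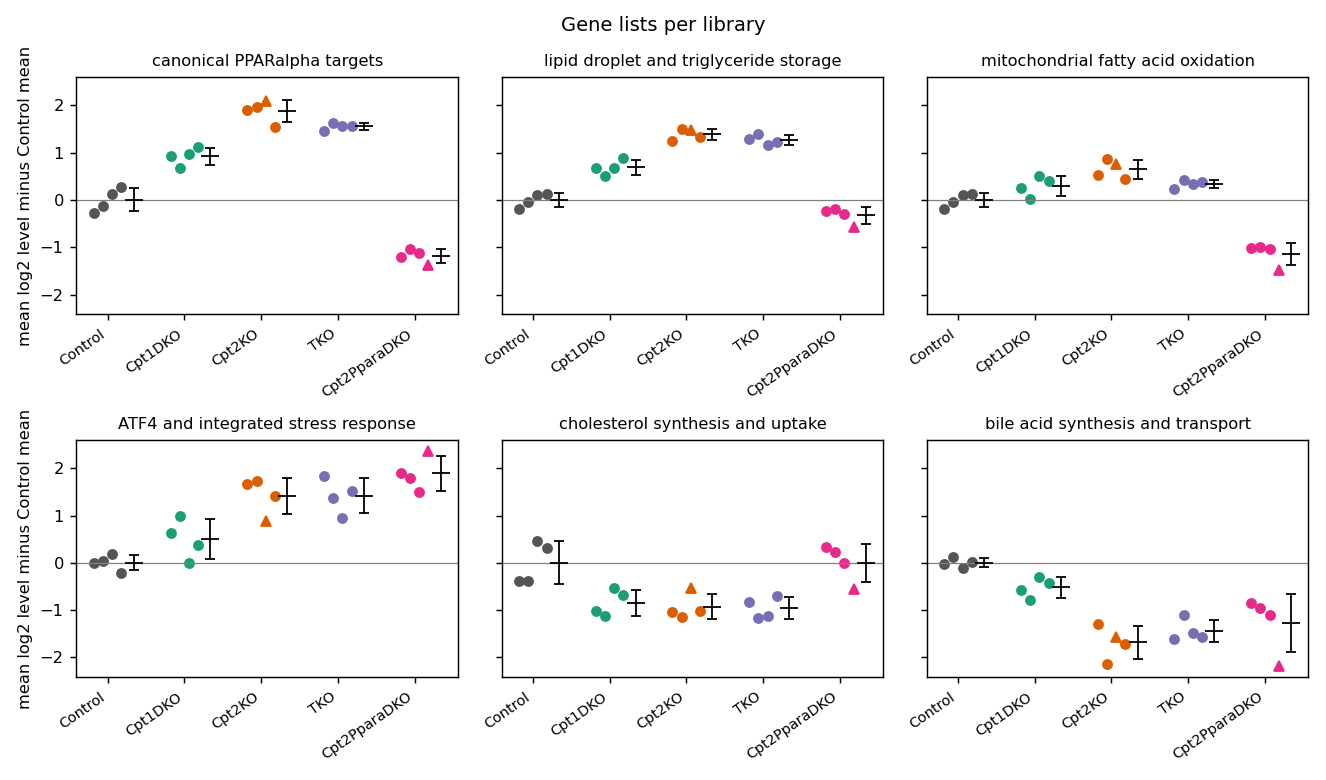
Mean log2 level of the tested members of 6 gene lists in each library, less the mean of the Control libraries (vertical axes, log2 units), by group, with a dot for each library, a triangle for each library with high Xist, and a bar for the mean ± SD of 4 libraries. The PPARalpha targets stood at 0.93 ± 0.18 in Cpt1DKO, 1.87 ± 0.23 in Cpt2KO, 1.55 ± 0.07 in TKO and -1.19 ± 0.14 in Cpt2PparaDKO.

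TKO against Cpt2KO tested the loss of Cpt1a and Cpt1b in livers without Cpt2. Besides Cpt1a itself (137 ± 12.7 against 1380 ± 191 CPM, SD, n = 4; log2 fold change -3.34, SE 0.19, adjusted p = 9.7e-10), few genes differed. Ide, the insulin-degrading enzyme, was lower, at 129 ± 18.4 against 259 ± 32.4 CPM (-1.01, SE 0.18, adjusted p = 0.0282), and Hivep2, a zinc finger transcription factor, was higher, at 16.5 ± 2.92 against 8.04 ± 1.66 CPM (1.04, SE 0.17, adjusted p = 0.0245). Each lost its call without Cpt2KO replicate 1, 2 or 4 or TKO replicate 2, 3 or 4 (adjusted p up to 0.205 for Ide and 0.115 for Hivep2). Fgf21 (-0.14, SE 0.47), Pdk4 (-0.45, SE 0.44) and Plin2 (-0.37, SE 0.22) were not called. Acot1 (-0.87, SE 0.20) passed in the authors' table, not here. Differences the size of these standard errors were undetectable.

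As lists, genes of mitochondrial fatty acid oxidation were lower in TKO than in Cpt2KO (0 of 22 called, 2 lower adjusted over the list alone; median -0.32, adjusted p = 7.7e-08, but 0.499 with an estimated correlation). PPARalpha targets were lower too (0 of 36 called, 2 lower over the list alone; median -0.28, adjusted p = 7.7e-06, but 0.499 with an estimated correlation), as was nuclear-encoded oxidative phosphorylation (0 of 29 called, 1 lower over the list alone; median -0.21, adjusted p = 7.4e-08, but 0.499 with an estimated correlation). Its median was -0.13 without Cpt2KO replicate 2. The mitochondrial DNA transcripts were higher (0 of 13 called, 2 higher over the list alone; median 0.32, adjusted p = 7.7e-06, but 0.499 with an estimated correlation), with a median of 0.20 with sex as a term. The list of peroxisomal oxidation and biogenesis was lower (0 of 23 called, 0 over the list alone; median -0.24, adjusted p = 7.2e-04, but 0.499 with an estimated correlation). So were the macrophage and Kupffer markers (0 of 20 called, 0 over the list alone; median -0.39, adjusted p = 4.9e-04, but 0.531 with an estimated correlation). Their median was -0.21 with sex as a term. Their call was lost without the female library, Cpt2KO replicate 3 (median -0.09, adjusted p = 0.294), without both female libraries (-0.10, adjusted p = 0.28) and without TKO replicate 1 (-0.25, adjusted p = 0.0707). NRF2 targets were higher (0 of 20 called, 1 over the list alone; median 0.30, adjusted p = 0.00785, but 0.531 with an estimated correlation). These lost their call in the same fits (median 0.11, 0.10 and 0.12, adjusted p = 0.504, 0.433 and 0.228). The list of lipid droplet and triglyceride storage was lower (0 of 19 called, 0 over the list alone; median -0.28, adjusted p = 0.0368, but 0.499 with an estimated correlation). It lost its call without Cpt2KO replicate 2 or 3, TKO replicate 3 or 4 or both female libraries and with only the 8 libraries compared (median -0.18 without Cpt2KO replicate 3, adjusted p up to 0.133).

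The edgeR test called 8 genes between TKO and Cpt2KO, 5 higher and 3 lower, against 1690 at an unadjusted p under 0.05 and 57 by DESeq2, and camera called 8 of 26 lists. The gene count was 5 with the replicate number as a block, 4, 3 and 4 without Cpt2KO replicate 1, 2 or 4, 3, 3 and 5 without TKO replicate 2, 3 or 4, and 16 without both female libraries. Another split of the same 8 libraries also called 5 genes. The number of lists was 5 without Cpt2KO replicate 3.

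TKO was also set against Cpt1DKO, which asks what the loss of Cpt2 adds where Cpt1 is already lost. Pdk4 stood at 562 ± 297 CPM in TKO and 68.5 ± 42.4 in Cpt1DKO (SD, n = 4; log2 fold change 3.04, SE 0.47, adjusted p = 0.00186), Fabp3 at 13.4 ± 9.43 against 0.233 ± 0.151 CPM (5.74, SE 0.74, adjusted p = 3.4e-04) and Gpnmb at 23.7 ± 3.18 against 1.68 ± 0.695 CPM (3.79, SE 0.37, adjusted p = 2.0e-05). Cyp7a1 was lower, at 17 ± 11 against 149 ± 35.4 CPM (-3.13, SE 0.45, adjusted p = 0.00104). Fgf21 (1.19, SE 0.48, adjusted p = 0.17) was not called.

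In TKO 8 of 36 canonical PPARalpha targets were higher than in Cpt1DKO (15 higher and 3 lower adjusted over the list alone; median 0.42, adjusted p = 6.9e-06, but 0.166 with an estimated correlation). Their median was 0.27 without Cpt1DKO replicate 2 and 0.26 without TKO replicate 2. Lipid droplet genes were higher in 3 of 19 (11 over the list alone; median 0.32, adjusted p = 4.3e-06, but 0.0661 with an estimated correlation), and NRF2 targets in 5 of 20 (8 over the list alone; median 0.63, adjusted p = 2.6e-08, but 0.166 with an estimated correlation). Urea cycle genes were lower in 2 of 14 cases (10 over the list alone; median -0.61, adjusted p = 2.6e-08, but 0.152 with an estimated correlation). Bile acid genes were lower in 6 of 18 (7 over the list alone; median -0.48, adjusted p = 6.7e-07, but 0.166 with an estimated correlation).

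In TKO against Cpt1DKO Gpnmb and Cd68 were higher, but the macrophage list was not called. The endothelial markers (0 of 14 called, 0 adjusted over the list alone; median -0.40, adjusted p = 1.5e-04, but 0.441 with an estimated correlation) were called as a list. So were the stellate and matrix markers (0 of 20 called, 0 over the list alone; median -0.28, adjusted p = 0.00141, but 0.166 with an estimated correlation). The cholangiocyte markers (1 of 12 lower, 1 over the list alone; median -0.81, adjusted p = 0.0391, but 0.441 with an estimated correlation) lost their call without Cpt1DKO replicate 2 (median -0.20, adjusted p = 0.219) or TKO replicate 1 or 2 (adjusted p = 0.0579 and 0.0823). A replicate block did the same (adjusted p = 0.053). The mitochondrial DNA transcripts were higher (0 of 13 called, 0 over the list alone; median 0.29, adjusted p = 0.0158, but 0.535 with an estimated correlation). Their call was lost without TKO replicate 3 (median 0.18, adjusted p = 0.17). In all, 729 genes were called, 407 higher and 322 lower, and 12 of 26 lists. The count was 379, 329 and 288 without Cpt1DKO replicate 1, 3 or 4 and 278, 465 and 438 without TKO replicate 1, 3 or 4.

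The interaction tested whether the effect of losing Cpt2 differed between livers with and without Cpt1a and Cpt1b. Cidec had an interaction log2 fold change of -3.67 (SE 0.29, adjusted p = 4.3e-07), Acot1 of -2.63 (SE 0.29, adjusted p = 3.5e-05), Pdk4 of -3.47 (SE 0.65, adjusted p = 0.00939) and Plin2 of -2.02 (SE 0.31, adjusted p = 0.00162), so that the level of these genes in TKO lay below the sum of both separate changes on the log2 scale. Thrsp (3.47, SE 0.43, adjusted p = 2.3e-04) lay above that sum. Lepr, the leptin receptor gene (-5.14, SE 0.91, adjusted p = 0.00767), Dusp8, a phosphatase of MAP kinases (-4.02, SE 0.77, adjusted p = 0.0113), and Cgref1 (-3.74, SE 0.33, adjusted p = 2.4e-06) lay below it. These genes kept their calls in all 16 fits with a library left out.

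Of 36 PPARalpha targets, 11 had a negative interaction (19 adjusted over the list alone; median -1.06, adjusted p = 1.7e-25, and 0.00223 with an estimated correlation). So did 5 of 19 lipid droplet genes (11 negative and 1 positive over the list alone; median -0.72, adjusted p = 1.1e-11, and 0.00223 with an estimated correlation) and 6 of 22 genes of mitochondrial fatty acid oxidation (8 over the list alone; median -0.47, adjusted p = 2.3e-09, but 0.302 with an estimated correlation). Cholesterol genes had a positive median of 0.81 (0 of 25 called, 5 positive over the list alone; adjusted p = 2.0e-07, but 0.32 with an estimated correlation). Acute phase genes had one of 0.79 (2 of 20 positive, 7 over the list alone; adjusted p = 3.8e-06, but 0.142 with an estimated correlation). The test called 423 genes, 222 positive and 201 negative, and 16 of 26 lists. The count was 259, 230, 244 and 246 without Control replicate 1, 2, 3 or 4, 178 and 209 without Cpt1DKO replicate 1 or 2, 205 without Cpt2KO replicate 2, 281 and 221 without TKO replicate 2 or 3, and 973 without both female libraries.

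Other lists were called for the interaction with few members called. The endothelial markers were negative (0 of 14 called, 0 adjusted over the list alone; median -0.51, adjusted p = 4.2e-04, but 0.443 with an estimated correlation). Their median was -0.80 without Control replicate 1. Negative too were peroxisomal oxidation and biogenesis (4 of 23 negative and 1 positive, 9 and 1 over the list alone; median -0.51, adjusted p = 1.9e-04, but 0.32 with an estimated correlation) and ketogenesis (1 of 6, 2 over the list alone; median -0.44, adjusted p = 0.0109, but 0.226 with an estimated correlation). So was the ATF4 and integrated stress response (2 of 23, 4 over the list alone; median -0.44, adjusted p = 0.00675, but 0.439 with an estimated correlation). Its median was -0.71, -0.29, -0.68 and -0.74 without Control replicate 3, Cpt1DKO replicate 2, Cpt1DKO replicate 3 and TKO replicate 4. Positive were de novo lipogenesis (3 of 16 and 1 negative, 7 and 4 over the list alone; median 0.62, adjusted p = 0.0115, but 0.302 with an estimated correlation) and the circadian clock (0 of 17 called, 0 over the list alone; median 0.45, adjusted p = 0.00667, but 0.32 with an estimated correlation). The list of bile acid synthesis and transport (1 of 18 positive, 1 over the list alone; median 0.56, adjusted p = 0.0126, but 0.45 with an estimated correlation) lost its call without TKO replicate 2 (adjusted p = 0.0548).

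The weakest calls of the interaction were those of NRF2 targets (2 of 20 positive, 3 adjusted over the list alone; median 0.14, adjusted p = 0.0249, but 0.567 with an estimated correlation) and nuclear-encoded oxidative phosphorylation (0 of 29 called, 0 over the list alone; median -0.13, adjusted p = 0.043, but 0.708 with an estimated correlation). The former was lost without Cpt1DKO replicate 3, Cpt2KO replicate 3, TKO replicate 1 or both female libraries (median 0.05 to 0.06, adjusted p up to 0.295). The median was 0.08, 0.24 and 0.22 without Control replicate 1, Cpt1DKO replicate 2 or Cpt2KO replicate 4. The latter was lost without Control replicate 1, Cpt1DKO replicate 3 or 4, Cpt2KO replicate 2 or 4 or TKO replicate 1, 3 or 4 (adjusted p up to 0.321). Its median was -0.08 and -0.04 without Cpt1DKO replicate 3 or Cpt2KO replicate 2.

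The changes of the mutant groups were then set side by side across 15669 genes, which are not independent replicates. Log2 fold changes against Control correlated at r = 0.72 between Cpt1DKO and Cpt2KO, at r = 0.88 between Cpt2KO and TKO and at r = 0.57 between Cpt2KO and Cpt2PparaDKO. Shared controls alone gave 0.50, 0.51 and 0.52 for unchanged groups, and with the controls split between the comparisons the mean observed values were 0.55, 0.75 and 0.47. The covariances were 0.40, 0.71 and 0.48 against 0.07 in each simulation, and 0.35, 0.66 and 0.43 with split controls. Of the genes called in Cpt1DKO and Cpt2KO, 335 rose in both and 449 fell in both, against 62 and 83 for independent lists and, here as in the next pairs, 0 in the same direction for unchanged groups. With the controls split, where fewer genes pass, 72 to 128 rose and 80 to 163 fell in both. Between Cpt2KO and TKO 1671 rose and 1856 fell in both (329 and 387 for independent lists; 871 to 954 and 1132 to 1165 still did with split controls). Between Cpt2KO and Cpt2PparaDKO 1211 rose and 1405 fell in both (377 and 474 for independent lists; 620 to 659 and 801 to 877 still did with split controls), 165 rose in Cpt2KO and fell in Cpt2PparaDKO, and 59 did the opposite. Of the genes that rose in Cpt2KO against Control, 865 were lower in Cpt2PparaDKO than in Cpt2KO (311 for independent lists), and of those that fell, 902 were higher (327). Unchanged groups gave a mean of 0.1 genes in opposite directions. With the Cpt2KO libraries split, 495 to 620 and 355 to 575 remained. The shared Cpt2KO libraries enter that comparison with opposite signs, and the correlation of -0.52 stood beside -0.50 for unchanged groups. With these libraries split between the comparisons its mean was -0.39. The covariance was -0.42 against -0.06 in the simulation, and -0.36 with split libraries.

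In the authors' deposited tables, 2153 genes passed an adjusted p of 0.05 for Cpt1DKO against Control, 4928 for Cpt2KO, 5303 for TKO and 5451 for Cpt2PparaDKO. The numbers called both there and here were 854, 4520, 4160 and 4691, all with the same direction. For TKO against Cpt2KO the authors' deposited table called 49 genes, which held all 8 called here.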

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

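The tests of another genotype, a lower share of hepatocytes, male-biased genes, and scaling, the female library and an upper limit behind the interaction of PPARalpha targets were chosen only after the results were seen, as was leaving out both female libraries. Within groups, 8 of 80 sets of 4 libraries held a value far from the other 3, where chance gives about 1 in 20. Cpt1a stood at 468 CPM in Cpt2PparaDKO replicate 4 against 920 to 1010 in the rest of its group. Cpt2 was 147 CPM in Cpt1DKO replicate 2 against 284 to 302, within Cpt2KO (114 to 165). Its Cpt1a (146) argues against Cpt2KO (1190 to 1620). Pdk4 stood at 13.4 CPM in Control replicate 3 against 6.08 to 7.24. Xist stood at 981 CPM in Cpt2KO replicate 3 against 0.461 to 0.945, and at 1270 CPM in Cpt2PparaDKO replicate 4 against 0.165 to 0.58. The total count of Cpt2PparaDKO replicate 1 was 36.5 M against 17.9 to 20 M. The TMM factor was 0.924 in Control replicate 1 against 0.841 to 0.854, and 1.29 in Cpt2PparaDKO replicate 4 against 1.17 to 1.19.

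Cpt2PparaDKO replicate 4 lay apart from the other libraries of its group, at 39.4 on component 1 against -10.4 to -3.19. A library of another genotype under this name was argued against, since Cpt2 stood at 28.5 CPM and Ppara at 54.3, below the lowest library of the other groups (92.5 and 170). A lower share of hepatocytes with more RNA of every other cell type was argued against too, since cholangiocyte markers were higher by 1.85 than in the mean of the others, which was 1.84 above the next of 6 lists of other cell types, and no list ranged over more than 1.61 among the other libraries. RNA of single other cell types, such as those of bile ducts, stays open, because 3 of the 6 lists were lower in it, but macrophage and Kupffer markers (-0.03) and endothelial markers (-0.01) by less than the spread of the others, and most lymphocyte markers (-0.36) are near the floor. Sex, the only biological explanation tested, stays open as well, because the deviations of both Xist-positive libraries correlated at r = 0.16 across 15188 autosomal genes, which are not independent, within the range of -0.24 to 0.31 of 159 other pairs, and 1 female library in the group cannot separate sex from the animal.

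The effect of losing Cpt2 differed with and without Cpt1a and Cpt1b for 423 genes and 16 lists by the test of the interaction, and canonical PPARalpha targets had a median interaction of -1.06. Normalization of libraries of different composition was argued against as the whole cause, since a factor per library moves every gene alike while the median of the list lay at -1.07 from that of all other genes. The female library in Cpt2KO was argued against too, since the median was -0.97 without it. An upper limit to the level these genes reach may account for the interaction, but it cannot be told apart from a smaller effect in TKO, because the list's median in TKO against Cpt2KO was -0.28 and its call there was lost with an estimated correlation (adjusted p = 0.499). The design gives a biological explanation, an effect of Cpt2 loss that depends on CPT1, which stays open beside the upper limit.

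Among single genes the interaction log2 fold change was 3.47 for Thrsp, -5.14 for Lepr, -4.02 for Dusp8, -3.74 for Cgref1, -3.47 for Pdk4, -2.63 for Acot1 and -2.02 for Plin2, and these calls held whichever library was left out. It was 4.09 for Cyp2c70, 3.98 for Car3, 3.96 for Ppp1r3c, 3.02 for Cyp2c54, -5.76 for Tubb2b, -5.29 for Ppp1r3g and -3.27 for Fgf21. Cyp2c54 lost its call without Cpt1DKO replicate 1 (adjusted p = 0.0547), and Fgf21 without Control replicate 1 or 4, Cpt1DKO replicate 1 or 2 or TKO replicate 3 (adjusted p up to 0.0555). Cyp2c70, Car3, Ppp1r3c, Tubb2b and Ppp1r3g lost theirs in 9, 15, 11, 9 and 8 of 16 fits.

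Female animals in the mutant groups may account for the female-biased genes in Cpt2PparaDKO, whose median log2 fold change against Control was 1.43 over 14 genes with all libraries and -0.45 over 13 without both female libraries, although the list was called in neither fit (adjusted p = 0.234 and 0.998). Cyp2a4 ranged from 5.74 to 117 CPM in the male libraries of Cpt2PparaDKO, from 0.405 to 2.69 in Control, and stood at 2050 in the female library, so the male libraries were higher as well. For male-biased genes among the falls female animals were argued against as the whole cause in Cpt1DKO, since it and Control held no female library and 7 of 19 (36.8%, against 5.62% of all genes) were called lower in the fit of male libraries, although 0 were with all libraries, at a median of -1.11 in either. In Cpt2KO, TKO and Cpt2PparaDKO 12, 9 and 5 were called lower in that fit and 7, 2 and 4 with all libraries. The list was called in each of the 4 groups in that fit (adjusted p = 5.9e-09, 7.5e-05, 0.00113 and 0.0143) but not in TKO with all libraries (adjusted p = 9.2e-04, 9.2e-04, 0.0674 and 0.0156) or anywhere with an estimated correlation (0.265 to 0.768), and no biological explanation was tested.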

How the results depend on the processing

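Both female libraries were left out only after seeing the data. No median of PPARalpha targets or called named gene changed sign in any fit, but a macrophage median did. Of 139 alternative counts of called genes 99 were within 1.5 times the reported count, as were 128 of 139 counts of called lists, and 101 of 103 medians of PPARalpha targets kept their call. Of 16678 values of named genes 15641 kept their side of the threshold, 788 lost a call and 249 gained one. The cause was not tested except where fewer libraries entered the fit.

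With an estimated inter-gene correlation, camera called 2 lists in Cpt1DKO, 2 in Cpt2KO, 2 in TKO and 3 in Cpt2PparaDKO against Control, 1 in Cpt2KO against Cpt1DKO, 7 in Cpt2PparaDKO against Cpt2KO, 0 in TKO against Cpt2KO, 0 in TKO against Cpt1DKO and 2 for the interaction. The medians of canonical PPARalpha targets of 0.65 in Cpt2KO against Cpt1DKO (adjusted p = 0.101) and of -0.28 in TKO against Cpt2KO (adjusted p = 0.499) were then not called. Nor was that of 0.42 in TKO against Cpt1DKO (adjusted p = 0.166), which is not among the 103 medians. DESeq2 called 1417 genes in Cpt1DKO against Control, 57 in TKO against Cpt2KO, 1267 in TKO against Cpt1DKO and 934 for the interaction. With only the 8 libraries compared, 1442 genes were called in Cpt1DKO against Control, 1344 in Cpt2KO against Cpt1DKO, 2495 in Cpt2PparaDKO against Cpt2KO and 5 in TKO against Cpt2KO. Without both female libraries 16 genes and 5 lists were called in TKO against Cpt2KO, of which 6 genes were shared, and 973 genes for the interaction, of which 419 were shared.

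Replicate numbers did not pair the libraries. Deviations of 40 pairs of libraries with the same number correlated at a mean r of 0.00, from -0.20 to 0.23, with 4 above 0.1, and 3 of 20 libraries correlated best with one of their own number.

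With 1 library left out, the number of called genes ranged from 288 to 1188 in Cpt1DKO against Control, from 1192 to 2517 in Cpt2KO against Cpt1DKO, from 3 to 10 in TKO against Cpt2KO, from 278 to 898 in TKO against Cpt1DKO and from 178 to 585 for the interaction. The number of lists ranged from 5, without Cpt2KO replicate 3, to 10 in TKO against Cpt2KO. The other counts stayed within 1.5 times, at 4347 to 5183 genes in Cpt2KO, 3394 to 3785 in TKO and 4158 to 4876 in Cpt2PparaDKO against Control, and 2997 to 4075 in Cpt2PparaDKO against Cpt2KO. A sex term called 308 genes but rests on 2 libraries. In the simulated Cpt1DKO comparison 19.4% of genes changed 1.5-fold and 93.9% of those changed 4-fold were called, so small changes were often missed there.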

Other observations

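The test of genes near floxed loci was chosen only after the results were seen. Genes of gluconeogenesis and fasting glucose, which make and release glucose, were lower in TKO than in Cpt1DKO (2 of 17 lower, 5 adjusted over the list alone; median -0.71, adjusted p = 4.9e-06, but 0.199 with an estimated correlation). Genes of hepatocyte secreted proteins were lower there as well (7 of 24 lower, 10 adjusted over the list alone; median -0.42, adjusted p = 9.6e-07, but 0.166 with an estimated correlation). Genes of the ATF4 and integrated stress response were higher in 5 of 23 cases and lower in 1 (10 and 1 adjusted over the list alone; median 0.90, adjusted p = 8.8e-05, but 0.199 with an estimated correlation). Their median was 0.59 without Cpt1DKO replicate 4 and 0.50 without TKO replicate 1.

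Cpt1b, the isoform of muscle, rose in Cpt2KO (log2 fold change 2.86, adjusted p = 9.4e-06) and in TKO (2.37, adjusted p = 1.1e-04) against Control from a low level, and was lower in Cpt2PparaDKO than in Cpt2KO (-2.75, adjusted p = 8.5e-06). The stellate and matrix markers had a negative interaction (1 of 20 negative, 2 adjusted over the list alone; median -0.49, adjusted p = 4.9e-04, but 0.147 with an estimated correlation), and mitochondrial DNA transcripts a positive one (0 of 13 called, 1 positive adjusted over the list alone; median 0.51, adjusted p = 0.00414, but 0.45 with an estimated correlation).

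Every count of called genes was set against other splits, in fits of only the libraries compared. The real groups were 1 of 35 splits, the least possible, in the next comparisons. Against Control they called 1442 genes in Cpt1DKO (highest other 1), 4574 in Cpt2KO (0), 5033 in TKO (0) and 4824 in Cpt2PparaDKO (0). They called 1344 in Cpt2KO against Cpt1DKO (0), 2495 in Cpt2PparaDKO against Cpt2KO (3) and 877 in TKO against Cpt1DKO (1). For TKO against Cpt2KO 2 of 35 splits called as many, at 5 genes each, so chance was not excluded. For the interaction 1 of 100 did (600 genes, at most 5 in the others). Those splits mix the separate losses too, and cannot exclude chance.

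By the labels the control carried floxed Cpt1a, Cpt1b and Cpt2, so strain DNA carried along with the floxed alleles would raise the share of calls only near loci where a group differed from it. Within 10 Mb of such loci the odds ratio of a call was 1.12 in Cpt1DKO (near Cpt2, 95% interval 0.5 to 2.2), 0.94 in Cpt2KO (near Cpt1a and Cpt1b, 0.765 to 1.15) and 1.1 in Cpt2PparaDKO (near Cpt1a, Cpt1b and Ppara, 0.919 to 1.32). Strain DNA stays open, because only 9 of 146 genes near Cpt2 were called in Cpt1DKO and the interval there is wide.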
